A study of Mus musculus with 27 samples.

How the data were processed

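Chromatin from mouse embryonic stem cells of the line HBG3 was profiled by ChIP-chip while the cells were turned into motor neurons. In this assay DNA recovered with an antibody against a histone is labelled and hybridised to an array of DNA probes. Antibodies against 3 modifications were used. H3K27me3 is deposited by Polycomb group proteins on silenced genes, H3K4me3 lies at active and poised promoters, and H3K79me2 lies over the start of transcribed genes. Per the labels, every array held the DNA recovered with one of these antibodies in Cy5 and the DNA recovered with an antibody against histone H3, at the same stage, in Cy3. There were 27 arrays of a custom Agilent design, 10 for H3K27me3, 11 for H3K4me3 and 6 for H3K79me2. They cover 6 stages. Days are counted from the start of cell aggregation (Day0), retinoic acid and a hedgehog agonist are added on Day2, and the stage called Day2+RA lies 8 hours after retinoic acid.

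The deposited table holds 1 processed value per array and feature, for features numbered 1 to 243504. The submitters' processing notes name Agilent Feature Extraction; its version, the background correction, the dye normalization and the genome build are not given in the sources used here. The dyes in the labels make each value a log ratio of the modification over H3. The deposited values were taken as log2 ratios, but neither the labels nor the table state the base of the logarithm, so differences are given as log ratios and never as folds. At the 99th percentile of the first H3K27me3 array the value would be an enrichment of 8.91-fold read as log2, 23.4-fold read as a natural logarithm and 1428-fold read as log10. Values ran from -6.08 to 7.79. The medians of the deposited columns were close to -0.10 for H3K27me3, -0.07 for H3K4me3 and -0.24 for H3K79me2.

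Arrays of one modification had nearly identical sorted values in the deposited table. Below the highest values, the number of probes above a level was therefore almost fixed on each array, whatever the total amount of the modification in the cells. The top of the range differed on Day2+RA: the highest deposited value was 4.40 and 4.86 for H3K27me3 (7.79 on all other arrays) and 5.10 and 5.81 for H3K4me3 (6.60 on all others). Replicate 1 of that stage lacked 181 values for H3K27me3 and 321 for H3K4me3. On the other stages these probes had median log ratios of -0.22 and -0.03, and none had a mean at 1 or more. That does not tell what they read on the 2 arrays that lack them. Those arrays had fewer probes at 1 or more, 24980 for H3K27me3 and 20095 for H3K4me3. On replicate 2 of that stage the numbers were 25127 and 20396. A rise at some probes is balanced by falls elsewhere, and a global gain or loss between stages cannot be read from these values.

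The table does not pair its feature numbers with genes, positions or sequences, so each probe was analysed by itself. Values of neighbouring feature numbers were uncorrelated on every array (r from -0.0029 to 0.027), so runs of neighbouring numbers were not joined either. The design fixed before the data were examined asked for gene means, promoter windows, tests of gene lists and a test of the order of Hox genes; these need gene names and were not run. Control spots could not be told from other features by number and were not removed. No scanner intensities were used here, so signal over background, dim spots and slides were not examined, and the number of arrays sets the precision.

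Each array was centred on its median over all probes. Changes of H3K27me3 and H3K4me3 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 model per modification with stage as the factor and all arrays of that modification. The spread is shared over stages, and stages with 1 array were assumed to vary like the others. For each modification 6 contrasts were tested, each adjusted by Benjamini-Hochberg over its probes, and a probe was called at adjusted p under 0.05. Probes with a value on every array of the modification were tested, 243269 for H3K27me3 and 243160 for H3K4me3. H3K79me2 had 1 array per stage and no test. Comparisons between modifications used the 242843 probes with a value on all 27 arrays, which left out 661. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

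A probe was described as marked where its stage mean, centred, was at least 1. Sets of called probes were followed across the 3 modifications, and their change in another modification was tested with fry from limma, two-sided, with Benjamini-Hochberg adjustment over 10 such tests. The fry test asks whether a set moves on balance one way and does not compare it with other probes. An SD given with a set is the spread between array means over all its probes. Averaging over many probes, the equalised distributions and choosing a set on the same arrays can keep this SD small. It does not measure the spread of single probes or of cultures. For H3K79me2 the median change of a set was placed among 10000 random sets of the same size matched on mean value. The rule for naming features, fixed in advance, took the 10 largest rises and 10 largest falls per contrast among called probes that moved the same way in every pairing of arrays. As the numbers name no gene, the largest rise and fall of a single contrast per modification are printed and the others are summarised.

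The fits were tested on simulated data made from the observed means and spreads, with 100 probes changed by 1 and 100 by 2 in each contrast. Of the changes of 2, the fit of Day4 against Day2 recovered 63 for H3K27me3 and 91 for H3K4me3, and of the changes of 1 it recovered 1 and 5. For H3K27me3 no simulated change of 1 or 2 was recovered in the contrasts of Day3 and Day7, which have 1 array each. No recovered change had the wrong sign, and false calls ranged from 0 to 12 per contrast. The real H3K27me3 fits of Day3 and Day7 against Day2 called 25334 and 2397 probes. The simulation, with few changed probes, therefore does not describe these fits, and its rates of recovery and false calls do not carry over to them.

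Alternatives fixed before the data were examined were values without centring, arrays scaled to one spread, quantile normalization, eBayes with trend and robust settings, the replicate number as a block, a minimum change of 1, probes at 0.5 or more on average, fits of the compared stages alone, thresholds of 0.5 and 1.5 for marked probes, and each array left out in turn. Removal of 2 discordant H3K27me3 arrays (from the limma and fry tests), probe sets called without them, the class of probes from Day2+RA replicate 2 alone and other thresholds for H3K79me2 were added after seeing the data.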

Results

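Mouse embryonic stem cells differentiating into motor neurons were sampled at 6 stages, and the level of 3 histone modifications relative to histone H3 was read at 243504 array probes. The title of the series places the question on Hox genes and on the removal of Polycomb-associated modifications as motor neurons form. Hox genes could not be examined here, as the probes could not be paired with genes. H3K27me3 was measured on 2 arrays each for Day0, Day2, Day2+RA (8 hours of retinoic acid) and Day4, and on 1 array each for Day3 and Day7. H3K4me3 had the same arrays and a second one for Day7. H3K79me2 had 1 array for each stage, labelled replicate 1 on Day2+RA and replicate 2 on every other stage. Each array gave between 243183 and 243502 values.

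Most arrays resembled the other arrays of the same modification. Across probes, which are not independent replicates, replicate arrays of H3K27me3 correlated at 0.83 on Day0, 0.98 on Day2 and 0.95 on Day4. Replicates of H3K4me3 correlated between 0.77 (Day7) and 0.91 (Day2 and Day4). The H3K27me3 arrays of Day2+RA replicate 1 and of Day3 stood apart. Replicate 1 of Day2+RA correlated at 0.57 with replicate 2 of that stage, and the mean of all other H3K27me3 arrays correlated at 0.60 with it and at 0.58 with the Day3 array. The remaining H3K27me3 arrays correlated with each other between 0.69 and 0.98. Values that use these 2 arrays are named as such where they matter.

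**Figure D1:**
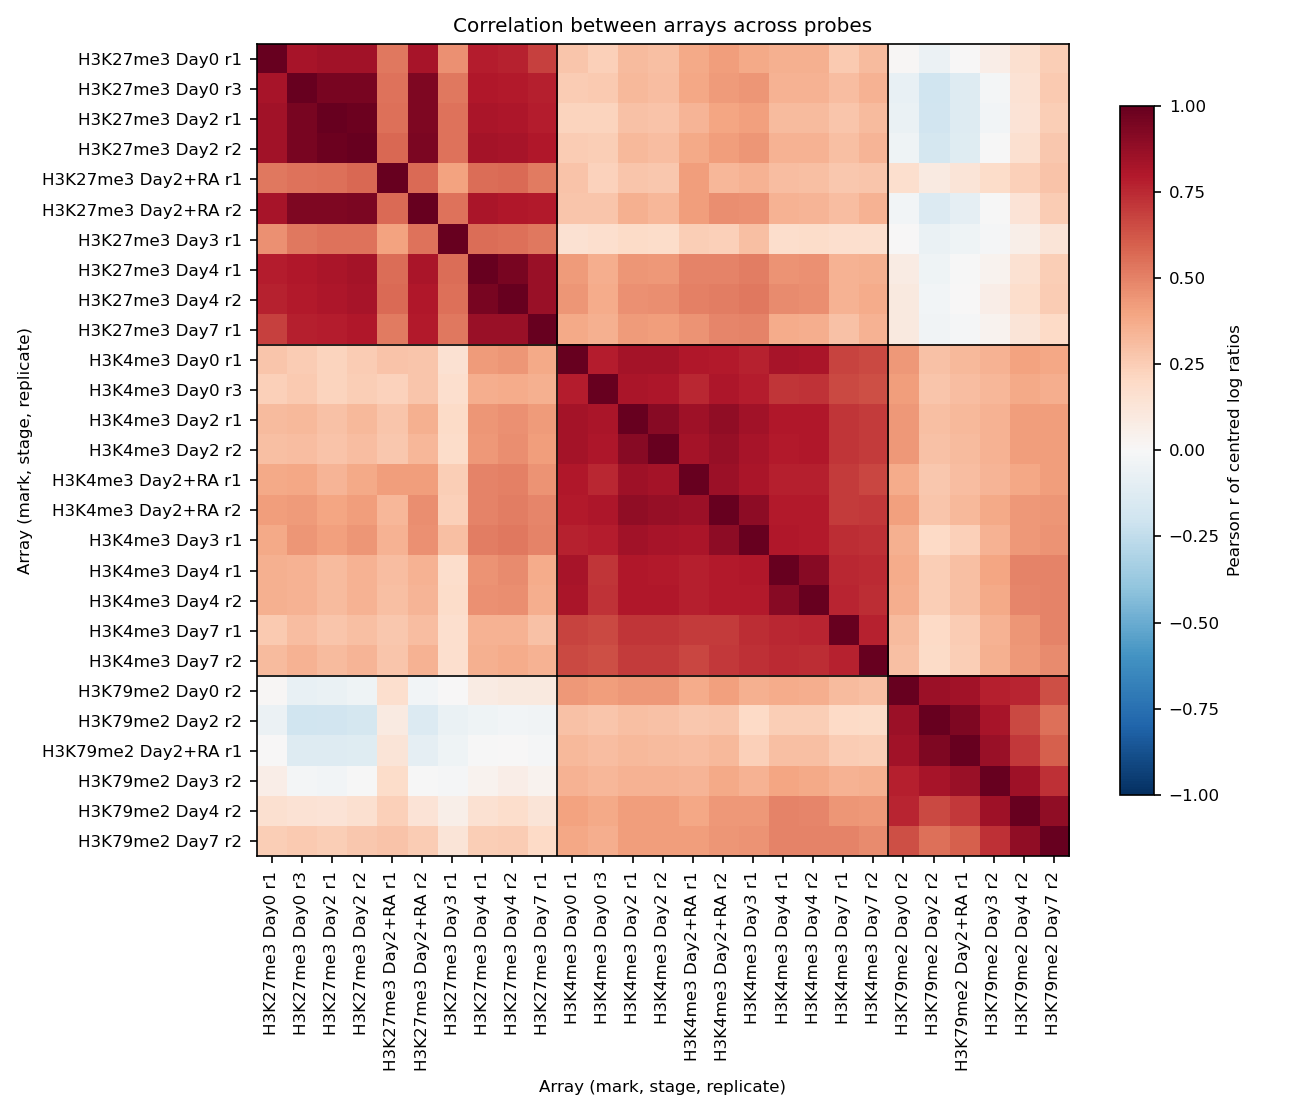
Pearson correlation across probes between all 27 arrays, ordered by modification, stage and replicate; the colour scale runs from -1 to 1 and lines part the modifications. The H3K27me3 arrays of Day2+RA replicate 1 and Day3 correlated at 0.57 or less with every other H3K27me3 array, and the lowest correlation between an H3K27me3 and an H3K79me2 array was -0.20.

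The comparison of Day2 with Day0 covers the first days of aggregation, before retinoic acid. No probe passed the limma test for H3K27me3 or for H3K4me3, while 5871 and 20763 probes, respectively, had an unadjusted p under 0.05. The 6244 probes marked by both modifications on Day0 had a mean H3K27me3 log ratio of 2.34 ± 0.11 (SD, n = 2) on Day0 and 2.25 ± 0.017 (n = 2) on Day2. Their H3K4me3 means were 2.18 ± 0.049 and 2.27 ± 0.058 (n = 2 each). The absence of calls rested on single arrays: for both modifications probes passed without Day0 replicate 3, and none passed without Day0 replicate 1. Each of these fits left 1 Day0 array. Day0 replicates 1 and 3 correlated with the mean of the other arrays at 0.84 and 0.92 for H3K27me3. For H3K4me3 these values were 0.87 and 0.84. The fit without replicate 3 thus kept the less similar H3K27me3 array. For H3K4me3, 112 passed without Day2 replicate 1, 12 without Day2 replicate 2, and 147 when only probes at 0.5 or more on average were adjusted.

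Within 8 hours of retinoic acid few probes were called for a change of H3K4me3. Between Day2 and Day2+RA it rose at 136 probes, with a median change of 2.03, and fell at 17, with a median change of -1.63. At the 135 rising probes with values on all arrays, the mean H3K4me3 log ratio went from 0.78 ± 0.0067 to 2.83 ± 0.020 (SD, n = 2 each). It was 2.56 on Day3, 2.86 ± 0.013 (n = 2) on Day4 and 2.58 ± 0.026 (n = 2) on Day7, on arrays outside the contrast that chose the set. On Day2, 98.5% of these probes were marked by H3K27me3, at a mean of 3.03 ± 0.0096 (n = 2). After 8 hours of retinoic acid the H3K27me3 mean was 2.32 ± 0.24 (n = 2), and 97.8% of the probes were still at 1 or more. This change of -0.71 passed the fry test at adjusted p = 0.00208, with both Day2+RA arrays (2.15 and 2.48) below both Day2 arrays. The lower value comes from the discordant replicate 1. Without it and the Day3 array the change was -0.54, from 1 array of Day2+RA. With both Day2+RA arrays, H3K27me3 was also lower at 24309 probes marked by it on Day2 and not called on Day4. There it changed by -0.36, to 1.67 ± 0.46 (n = 2), an SD larger than the change. Probe by probe, the 2 Day2+RA arrays differed by a median of 0.85 in this set. Of probes at 2 or more on all Day2 and Day4 H3K27me3 arrays, 4.56% lay under 0.5 on replicate 1. On replicate 2 the share was 0%. Whether a fall went beyond the 135 probes therefore stays open.

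H3K27me3 at the 135 probes was 1.36 on the discordant Day3 array, below the Day4 value. It was 1.92 ± 0.019 (n = 2) on Day4 and 0.97 on the single array of Day7. The changes from Day2, -1.11 and -2.05, each had an adjusted p of 5.6e-04 by fry. Here and below, a fry test of H3K27me3 on Day7 takes the spread of that stage wholly from the other stages. Their H3K79me2 log ratio was -0.10 on Day2, 1.64 after 8 hours of retinoic acid and between 2.20 and 2.24 on Day3, Day4 and Day7. The 10 largest H3K4me3 rises lay between 2.63 and 2.88. The largest, at probe 49356, was 2.88 (SE 0.32, limma adjusted p = 0.016), from -0.03 ± 0.26 to 2.85 ± 0.71 (SD, n = 2 each). The largest fall, at probe 10092, was -1.89 (SE 0.25, limma adjusted p = 0.0325), from 3.25 ± 0.12 to 1.37 ± 0.39 (n = 2 each). Both calls were lost without either Day2+RA array and without Day2 replicate 2, and the second also without Day2 replicate 1 or either Day4 array and with trend and robust settings.

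The 153 H3K4me3 calls became 0 without Day2+RA replicate 1, 2 without Day2+RA replicate 2, 15 without Day2 replicate 2 and 36 without either Day4 array. Without Day2 replicate 1 there were 216 calls, 64 rises and 152 falls, so the excess of rises was lost. The count was 71 with trend and robust settings and 1659 among probes at 0.5 or more on average, where 1047 rose and 612 fell. In the simulation this contrast recovered 2 of 100 changes of 1, so a small count does not show that few probes changed. At 2757 probes that gained H3K4me3 by Day4 its mean was 0.39 ± 0.031 on Day2 and 0.99 ± 0.022 on Day2+RA (SD, n = 2 each). At 1127 probes that lost it by Day4 the change was -0.12. Both sets were chosen with the same Day2 arrays. Between Day2 and Day2+RA no probe passed the limma test for H3K27me3, with 17924 at an unadjusted p under 0.05. Without Day2+RA replicate 1, 40 passed, 6 higher and 34 lower. Without Day2+RA replicate 2, which leaves the discordant array alone, 57609 passed, and 11 passed among probes at 0.5 or more on average.

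By Day4 H3K27me3 had fallen at 772 probes and risen at 963 compared with Day2. The 772 probes carried H3K27me3 at a mean log ratio of 2.24 ± 0.035 on Day0 and 2.37 ± 0.0011 on Day2 (SD, n = 2 each). They were at 0.74 ± 0.032 (n = 2) on Day4 and at 0.22 on Day7. On Day2+RA they were at 1.84 and 1.95 on the 2 arrays. H3K4me3 at the same probes rose from 0.43 ± 0.052 on Day2 to 1.71 ± 0.0037 on Day4 (n = 2 each), a change of 1.29 with a fry adjusted p of 3.16e-06. A part of that rise was present after 8 hours of retinoic acid (1.01 ± 0.073, n = 2; change 0.59, fry adjusted p = 9.72e-05). Their H3K79me2 log ratio was -0.05 on Day2, 0.55 on Day2+RA, 1.48 on Day3 and 1.81 on Day4.

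Of the 772 probes, 365 were also among the H3K4me3 rises of Day4 against Day2, where 8.76 would be shared by independent lists. H3K4me3 falls held 2 of them, with 3.58 for independent lists. Here and below, independent lists are drawn from all 242843 probes, whatever their marks on Day2. Shared starting marks can therefore give part of an excess. On Day2, H3K27me3 marked 87.2% of the 772 probes and 76.0% of the 2757 H3K4me3 rises with values on all arrays. At the 24309 probes that were marked by H3K27me3 on Day2 and not called on Day4, H3K27me3 was 2.03 ± 1.49e-04 on Day2 and 1.83 ± 0.026 on Day4 (n = 2 each). H3K4me3 was 0.67 ± 0.033 and 0.76 ± 0.0022 at these probes, and H3K79me2 was -0.05 and 0.35.

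The 958 probes with an H3K27me3 rise on Day4 and values on all arrays had low values before, at 0.25 ± 0.049 on Day2, and reached 1.76 ± 0.025 on Day4 (SD, n = 2 each). On Day7 they were at 1.44. On Day2, 71.1% of them were marked by H3K4me3. Their mean H3K4me3 log ratio was 2.02 ± 0.030 on Day2 and 1.86 ± 0.013 on Day4 (n = 2 each), a change of -0.16 that did not pass the fry test (adjusted p = 0.17). It was 1.41 ± 0.013 (n = 2) on Day7. H3K79me2 at these probes was 0.45 on Day2 and 0.37 on Day4. H3K4me3 falls on Day4 held 85 of them, where independent lists would share 4.45, and H3K4me3 rises held 1, with 10.9 for independent lists. On Day2, H3K4me3 marked 92.3% of the 1127 falls with values on all arrays and 8.07% of all probes. The excess of 85 over 4.45 is thus set against probes that mostly had no H3K4me3 to lose.

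**Figure D2:**
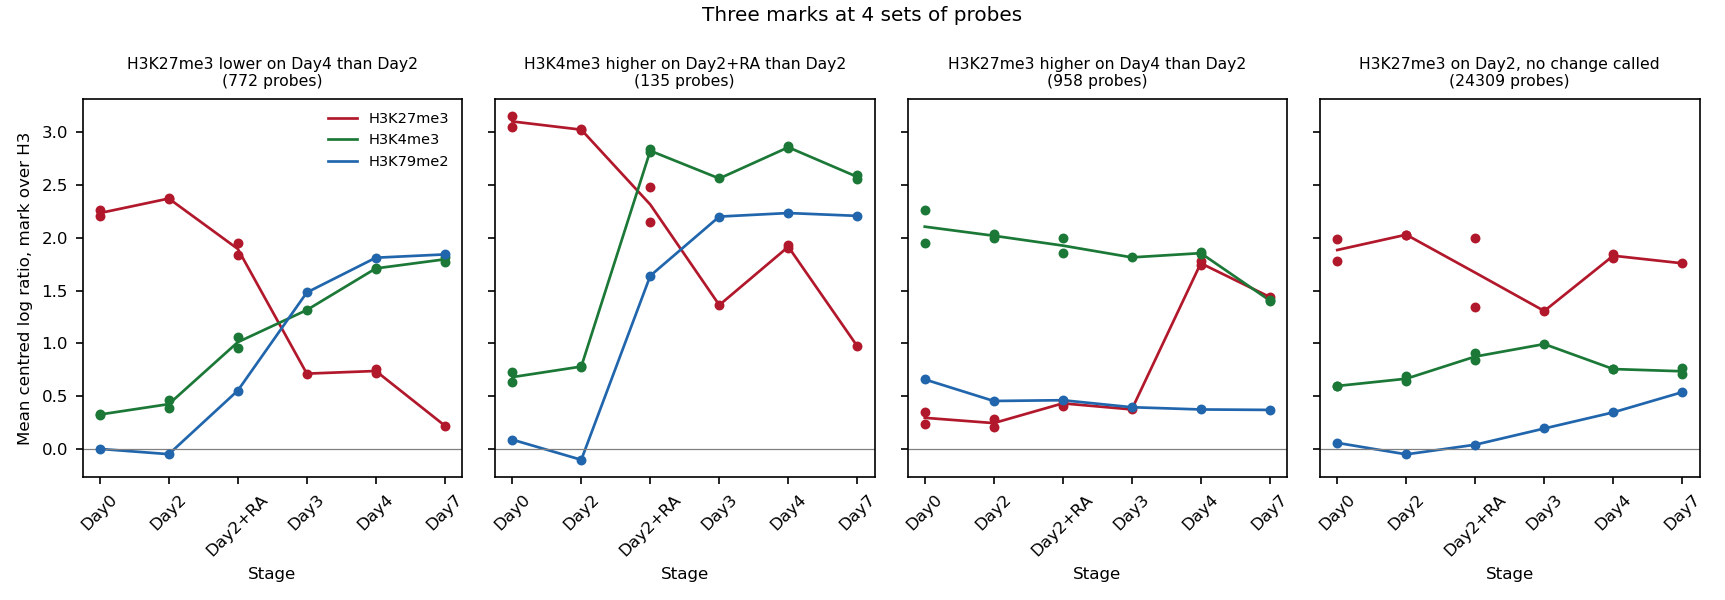
Mean centred log ratio (vertical axis) of the 3 modifications by stage (horizontal axis) at 4 sets of probes; each point is 1 array and lines join stage means. At the 772 probes with lower H3K27me3 on Day4, H3K27me3 went from 2.37 on Day2 to 0.74 on Day4, and H3K4me3 from 0.43 to 1.71. The Day2+RA points of H3K27me3 lie farthest apart in the set with no change called.

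The 10 largest H3K27me3 falls on Day4 lay between -3.18 and -2.81 and the 10 largest rises between 3.06 and 3.43. Probe 53540 went from 3.15 ± 0.030 to -0.03 ± 0.0049 (SD, n = 2 each), a change of -3.18 (SE 0.43, limma adjusted p = 0.0343). Probe 70882 went from 0.17 ± 0.11 to 3.60 ± 0.0030, a change of 3.43 (SE 0.39, limma adjusted p = 0.025). Like the counts, both calls were lost with trend and robust settings and without any one of the Day2 or Day4 arrays.

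The number of H3K27me3 calls depended on the settings of the fit and on which arrays and probes entered it. The 1735 calls of Day4 against Day2 became 0 with trend and robust settings and without any one of the Day2 or Day4 arrays. They became 25778 without Day2+RA replicate 1, 25793 without Day2+RA replicate 2, 4933 among probes at 0.5 or more on average and 80867 in a fit of the 4 arrays compared. In these 4 fits falls outnumbered rises, by 2549 to 2384 among probes at 0.5 or more on average and by 40927 to 39940 with the 4 arrays. With the 2 discordant arrays removed, 12256 probes rose and 13519 fell. The 13510 falling probes with values on all arrays changed less on average: H3K27me3 was 1.06 ± 0.023 on Day2 and 0.09 ± 0.027 on Day4 (n = 2 each), the H3K4me3 mean changed by 0.23 and the H3K79me2 mean by 0.47. H3K4me3 rises held 1398 of them, with 153 for independent lists. At 12232 rising probes of this fit H3K27me3 went from 0.08 ± 0.024 to 1.03 ± 0.019 (n = 2 each). Their H3K4me3 mean was 1.02 ± 0.0036 on Day2 and 1.09 ± 0.016 on Day4 (n = 2 each), a change of 0.07, opposite in sign to that of the 958 probes. H3K4me3 falls held 352 of the 12232, with 56.8 for independent lists, but H3K4me3 marked 40.1% of the 12232 on Day2. H3K4me3 rises held 209 of the 12232, with 139 for independent lists. The scarcity of rises among the 958 was thus not found in the wider set.

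On Day3, H3K27me3 was called at 14359 rising and 10975 falling probes, from 1 array that stood apart from all other H3K27me3 arrays. This count was 69877 without Day2+RA replicate 1, 69902 without Day2+RA replicate 2, 3334 and 3485 without Day2 replicates 1 and 2, 11609 without either Day4 array, and 9878 among probes at 0.5 or more on average, where 1273 rose and 8605 fell. The 772 probes that were lower on Day4 were at 0.71 on this array.

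On Day7, H3K27me3 was lower than on Day2 at 1503 probes (median change -2.41) and higher at 894 (median change 1.79). The falling probes went from 2.53 ± 0.0079 (SD, n = 2) to 0.08 on the single array, by way of 1.22 ± 0.030 (n = 2) on Day4. H3K4me3 at these probes was 0.52 ± 0.018 on Day2, 2.05 ± 0.0012 on Day4 and 2.10 ± 0.042 on Day7 (n = 2 each), and H3K79me2 was -0.11, 2.02 and 2.13. H3K4me3 rises of Day7 against Day2 held 945 of the 1503 probes, with 27.6 for independent lists. H3K4me3 falls held 243 of the 894 probes with more H3K27me3, with 14.3 for independent lists. With the 2 discordant arrays removed, the shared probes were 1891 of 7278 falling ones (26.0% in place of 62.9%; 134 for independent lists) and 743 of 5072 rising ones (14.6% in place of 27.2%; 81.4 for independent lists). Between Day4 and Day7, 8 probes rose and 7 fell in H3K27me3. All 8 rises had feature numbers from 88331 to 88880 or from 102554 to 102824. The falls at 88596 and 88609 lay in the same range. The 4 largest rises of Day7 against Day2 were among these 8 probes. Of the H3K27me3 arrays, the Day7 array had the highest correlation of residuals between neighbouring feature numbers (0.080). A local defect of that single array was not tested.

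The 2397 calls of Day7 against Day2 became 0 without either Day2 array, 521 without either Day4 array, 12362 and 12370 without Day2+RA replicates 1 and 2, 1372 with trend and robust settings and 4118 among probes at 0.5 or more on average. The 15 calls of Day7 against Day4 became 4 without either Day0 array, 0 without either array of Day2 or Day4, 2565 and 2567 without Day2+RA replicates 1 and 2, 23 with trend and robust settings and 159 among probes at 0.5 or more on average, where 40 rose and 119 fell. Without Day2+RA replicate 1, 1232 rose and 1333 fell.

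Compared with Day2, H3K4me3 rose at 213 and fell at 22 probes on Day3 (1 array), rose at 2767 and fell at 1129 on Day4, and rose at 4470 and fell at 3904 on Day7. The median rise was 1.92 on Day4 and 1.71 on Day7, and the median fall was -1.55 and -1.43. Of 4458 probes that gained H3K4me3 by Day7, 68.2% were marked by H3K27me3 on Day2. Their H3K27me3 mean was 1.71 ± 5.65e-05 (SD, n = 2) on Day2 and 0.64 on Day7, a change of -1.07 (fry adjusted p = 0.00214, 1 array on Day7). Their H3K79me2 log ratio was 0.01 on Day2 and 1.63 on Day7. At 3897 probes that lost H3K4me3 by Day7, H3K27me3 rose by 0.46, from 0.99 ± 0.0059 (n = 2) to 1.45 (fry adjusted p = 0.013, 1 array on Day7), and H3K79me2 was 0.60 on Day2 and 0.33 on Day7. Between Day4 and Day7, H3K4me3 rose at 1863 probes and fell at 1460.

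The 235 H3K4me3 calls on Day3 became 17 without Day2 replicate 2, 70 without either Day2+RA array, 4 without either Day4 array, 138 with trend and robust settings and 1531 among probes at 0.5 or more on average, where 1119 rose and 412 fell. Without Day2 replicate 1 there were 228, of which 72 were rises and 156 falls. The 3896 calls on Day4 became 2144 and 1827 without Day2 replicates 1 and 2, 1687 and 1747 without Day4 replicates 1 and 2, and 8785 in a fit of both stages alone. Among probes at 0.5 or more on average rises and falls on Day4 were nearly even, at 2976 and 2741. The 8374 calls on Day7 became 4092 and 3742 without Day2 replicates 1 and 2 and 5067 in a fit of both stages alone, fewer than the 8785 of Day4 in such a fit. Among probes at 0.5 or more on average falls outnumbered rises on Day7, with 4124 rises and 7561 falls, and without either Day0 array they were nearly even (5022 rises and 5070 falls). The 3323 calls of Day7 against Day4 became 0 in a fit of both stages alone, 7116 among probes at 0.5 or more on average, 6919 and 6916 without Day0 replicates 1 and 3, 1648 without either Day2 array, 2004 without either Day2+RA array, and 406 and 423 without Day4 replicates 1 and 2. Falls outnumbered rises in 3 of these fits: 4853 against 2263 among probes at 0.5 or more on average, and 4009 against 2910 and 4007 against 2909 without Day0 replicates 1 and 3.

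H3K79me2 was described without a test, since each stage had 1 array. The Day2+RA array was the only one labelled replicate 1, the number of the discordant H3K27me3 array of that stage. A difference between Day2+RA and another stage in H3K79me2 cannot be told from one between replicate numbers. Probes at 1 or more on one of the days compared were counted where they differed by at least 1. From Day0 to Day2 611 were higher and 660 lower. After 8 hours of retinoic acid 722 were higher than on Day2 and 23 lower, and on Day3 3522 were higher and 456 lower. On Day4 the numbers were 5681 and 3162, and on Day7 they were 9215 and 6053. With a difference of at least 0.5 the direction turned on both days, to 8333 higher and 10547 lower on Day4 and 11680 and 14394 on Day7. From Day4 to Day7, 3109 were higher and 328 lower by at least 1. The excess of higher probes was smaller at 0.5 in the other comparisons with Day2 and between Day4 and Day7: 1114 and 498 on Day2+RA, 5242 and 4125 on Day3, and 5703 and 3314 from Day4 to Day7. Between Day2 and Day7 the median H3K79me2 change of the 772 probes with lower H3K27me3 on Day4 was 2.35, at the 100th percentile of 10000 matched random sets, whose central 95% lay between -0.29 and -0.18. The 135 probes with the early H3K4me3 rise had a median change of 2.56 (100th percentile). Probes that lost H3K4me3 by Day7 had a median change of -0.17, at the 0th percentile of their random sets (-0.10 to -0.07). The median change was 1.94 at probes that gained H3K4me3 by Day7, 0.40 at probes with both marks on Day0 and 0.19 at those with H3K27me3 alone on Day0. It was 0.05 at probes with higher H3K27me3 on Day4 (random sets -0.10 to -0.03), while the mean of these probes went the other way, from 0.45 on Day2 to 0.37 on Day7. It was -0.13 at those with H3K4me3 alone on Day0 (random sets -0.19 to -0.16). Each of these 5 sets was at the 100th percentile, from a median of 1.94 down to one of -0.13, so the percentile does not rank sets by size; it describes these arrays and takes probes as independent.

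Probes that carry H3K27me3 and H3K4me3 together, often called bivalent in stem cells, were followed from Day0 in a population of cells, where both marks need not lie on the same chromosome. On Day0, 6244 probes were marked by both, 17835 by H3K27me3 alone and 12273 by H3K4me3 alone. Of the 6244, 83.1% had both on Day2, 70.5% on Day4 and 51.8% on Day7. On Day7, 30.2% had H3K27me3 alone, 15.5% had H3K4me3 alone and 2.42% had neither. Values for Day2+RA (78.7%) and Day3 (57.7%) rest in part or in full on discordant arrays, and with Day2+RA replicate 2 alone the first was 89.1%. Between replicate arrays of one stage the same measure was 70.4% and 63.2% on Day0, 83.2% and 89.1% on Day2 and 90.4% and 84.6% on Day4. The Day4 value lies next to the higher replicate value of Day0 and below every replicate value of Day2 and Day4. Replicate values come from single arrays, which vary more than stage means. The Day7 value lies below all of these replicate values, but it uses a single H3K27me3 array. On Day7, 82.1% of the 6244 probes were marked by H3K27me3 and 67.4% by H3K4me3. The 2 H3K4me3 arrays of Day7 correlated at 0.77. Their mean marked 16849 probes, against 20400 and 20398 on the single arrays. Averaging arrays that disagree can thus give part of the drop, and no replicate value was made for Day7.

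Over the 6244 probes as a set, H3K27me3 was 2.25 ± 0.017 on Day2 and 2.37 ± 0.015 on Day4 (SD, n = 2 each; change 0.13, fry adjusted p = 0.692). H3K4me3 was 2.27 ± 0.058 on Day2 and 2.14 ± 0.0020 on Day4 (n = 2 each; change -0.12, fry adjusted p = 0.0484), and 1.95 ± 0.049 (n = 2) on Day7. Of the 12273 probes with H3K4me3 alone on Day0, 3.15% had both marks on Day2, 21.0% on Day4 and 16.3% on Day7. The Day4 H3K27me3 arrays also resembled H3K4me3 more across all probes. They correlated at 0.43 and 0.44 with H3K4me3 of Day0 replicate 1, against 0.22 and 0.26 for the Day2 arrays. These values do not separate a shift of the whole array from a gain at these probes. The total number of probes with both marks was 6799 on Day2, 8416 on Day2+RA, 6945 on Day3, 9309 on Day4 and 6920 on Day7. The Day2+RA and Day3 totals use the discordant H3K27me3 arrays. With H3K27me3 from Day2+RA replicate 2 alone the total of that stage was 9284, so the higher number was not particular to Day4. The number of probes with H3K27me3 at 1 or more was 24079 on Day0, 25051 on Day2, 24708 on Day4 and 25162 on Day7, and for H3K4me3 it was 18517, 19598, 19879 and 16849; these totals are held close together by the equalised distributions, and a mean of 2 arrays gives fewer than a single one.

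**Figure D3:**
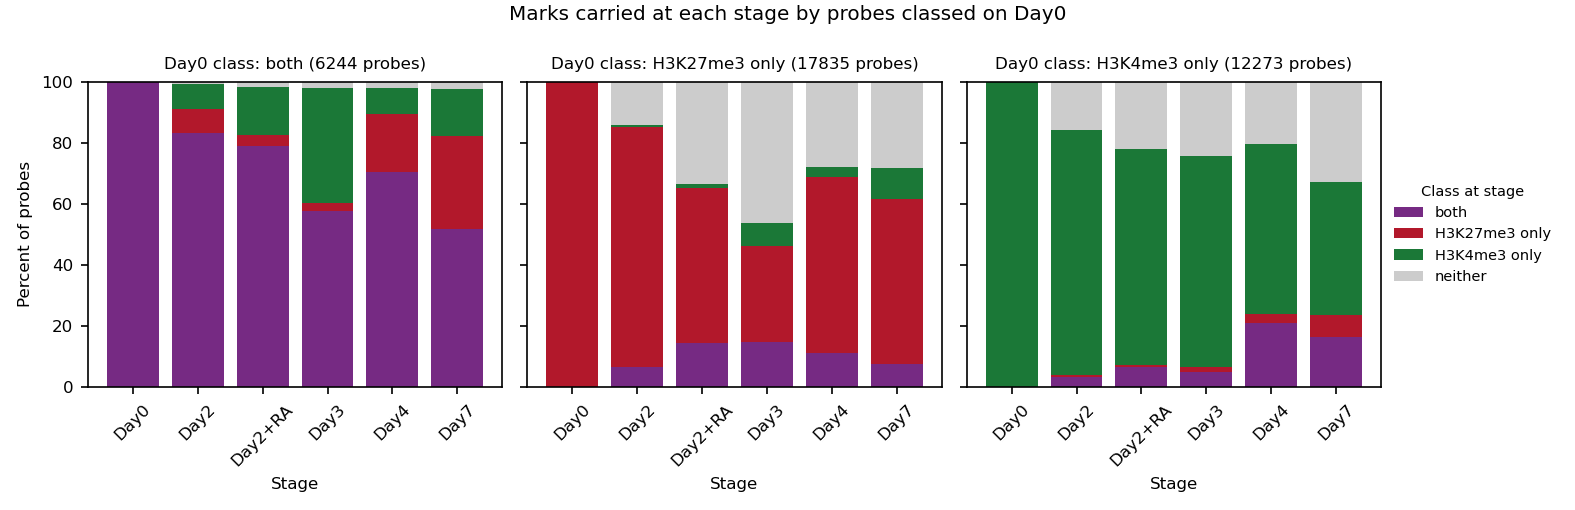
Percent of probes (vertical axis) in each class at each stage (horizontal axis), for probes with both marks, H3K27me3 alone or H3K4me3 alone on Day0; a mark counts where the stage mean is at least 1. Of the probes with both on Day0, 51.8% had both on Day7, and of those with H3K4me3 alone 21.0% had both on Day4.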

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

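Centring, scaling to one spread and quantile normalization kept every count of called probes within 1.5 times of the value given, and so did a minimum change of 1. The deposited arrays of one modification already had nearly identical sorted values. Centring and the scalings could therefore hardly move a count, and their agreement is no test of the normalization. Of the alternative counts of called probes, leave-one-out fits and these scalings included, 133 were within 1.5 times and 86 were not. For the 4 printed probes, the call held in 41 alternative fits, scalings included, and was lost in 23, with no change of sign. Causes were not tested unless named; fits of fewer arrays or adjusted probes differ by construction. With a spread shared over stages, H3K27me3 calls favour probes at which both Day2+RA arrays agree: the median absolute difference between these arrays was 0.27 at the 772 falling probes, 0.22 at the 958 rising ones, 0.38 at all probes and 0.85 at the 24309 probes not called. The 6 fry tests in H3K27me3 kept direction and side of the threshold without the 2 discordant arrays.

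Without each array in turn, H3K27me3 calls ranged from 0 to 1178 (Day2 against Day0), 0 to 57609 (Day2+RA against Day2), 3334 to 69902 (Day3 against Day2), 0 to 25793 (Day4 against Day2), 0 to 12370 (Day7 against Day2) and 0 to 2567 (Day7 against Day4). In the same order, H3K4me3 calls ranged from 0 to 548, 0 to 216, 4 to 332, 1687 to 5703, 3742 to 10092 and 406 to 6919.

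With the replicate number as a block, H3K27me3 calls were 6664 on Day3 against Day2 and 0 for Day4 against Day2, Day7 against Day2 and Day7 against Day4. For H3K4me3 the block gave 176 on Day2 against Day0, 90 on Day2+RA, 79 on Day3 and 5883 on Day7 against Day4, and no other count moved by over 1.5 times; on Day7 against Day4, 2557 rose and 3326 fell. Of the 4 printed probes, 70882, 53540 and 10092 were not called with the block and 49356 was. Same-numbered arrays of one modification deviated together with correlations from -0.11 to 0.12. Between modifications the range was -0.08 to 0.28, the highest for H3K27me3 and H3K4me3 on Day2+RA. As most pairs stayed under 0.1, the numbers were not taken to pair the samples.

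With eBayes trend and robust settings, H3K27me3 calls were 0 on Day4 and 1372 on Day7 against Day2 and 23 on Day7 against Day4; H3K4me3 calls were 71 on Day2+RA and 138 on Day3. Among probes at 0.5 or more on average, H3K27me3 calls were 11 on Day2+RA, 9878 on Day3, 4933 on Day4 and 4118 on Day7 against Day2, and 159 on Day7 against Day4. H3K4me3 calls were then 147 on Day2 against Day0, 1659 on Day2+RA, 1531 on Day3 and 7116 on Day7 against Day4. With the arrays of both stages alone, calls were 80867 for H3K27me3 on Day4 against Day2, and for H3K4me3 8785 on Day4, 5067 on Day7 against Day2 and 0 on Day7 against Day4. With the H3K27me3 arrays of Day2+RA replicate 1 and Day3 removed, chosen after seeing the data, calls were 40 on Day2+RA, 25775 on Day4 and 12362 on Day7 against Day2 and 2564 on Day7 against Day4. At the falling probes called that way, the Day2 to Day4 change was 0.23 for H3K4me3 and 0.47 for H3K79me2.

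At thresholds of 0.5 and 1.5, H3K27me3 marked 45817 and 15720 probes on Day0, 46632 and 16427 on Day2, 41782 and 13529 on Day2+RA, 47447 and 16413 on Day3, 45719 and 16354 on Day4, and 47445 and 16424 on Day7. At 0.5, H3K4me3 marked 36061, 39995, 38449, 42674, 38479 and 33999 in stage order. Both marks were found at 13892 and 3366 probes on Day0, 15093 and 3614 on Day2, 17689 and 4483 on Day2+RA, 14870 and 4008 on Day3, 22231 and 4880 on Day4, and 16752 and 3750 on Day7. The percent of Day0 probes with both marks that had both later was 76.7 and 80.5 on Day2, 74.1 and 71.8 on Day2+RA, 72.3 and 63.2 on Day4, 54.4 and 45.5 on Day7, and 53.9 at 0.5 on Day3. With H3K79me2 differences of at least 0.5 and 1.5, also chosen after seeing the data, the probes that differed numbered 7593 and 213 (Day2 against Day0), 1612 and 442 (Day2+RA), 9367 and 2338 (Day3), 18880 and 4697 (Day4), 26074 and 7967 (Day7 against Day2), and 9017 and 1303 (Day7 against Day4). At 0.5, probes with lower H3K79me2 outnumbered higher ones on Day4 (10547 against 8333) and Day7 (14394 against 11680) compared with Day2, the other way round from a difference of 1.

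Not run, for want of gene names or positions: other windows, minimum numbers of probes, the median of probes, gene lists and the Hox order. Signal over background, which limits arrays, was not examined.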

Other observations

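The tests of the discordant arrays on H3K79me2, on the second replicate, on a swap and on neighbouring features were chosen only after the result was seen. So were the removal of 2 arrays, the level of probes with missing values, the probe-by-probe difference of the Day2+RA arrays, the sets called without them, the class from Day2+RA replicate 2 alone and the H3K79me2 differences of 0.5 and 1.5.

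H3K4me3 also fell at some probes within 8 hours of retinoic acid, 17 of the 153 called, and 152 of 216 without Day2 replicate 1. The 17 probes at which it fell within 8 hours of retinoic acid had a mean of 2.98 ± 0.024 on Day2 and 1.34 ± 0.13 on Day2+RA (SD, n = 2 each). Their mean was 1.79 on Day3, 2.30 ± 7.53e-04 on Day4 and 2.01 ± 0.0083 on Day7 (n = 2 each for both days). Their H3K79me2 log ratio was 1.23 on Day2, 1.22 on Day2+RA and 1.25 on Day3. H3K27me3 at these probes was 0.24 ± 0.0021 on Day2, 0.85 ± 0.10 on Day4 (n = 2 each) and 0.71 on Day7.

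Of 17835 probes with H3K27me3 alone on Day0, 54.0% had H3K27me3 alone on Day7, 7.64% had both marks, 10.0% had H3K4me3 alone and 28.4% had neither, from 1 H3K27me3 array on Day7. On Day2, with no probe called in either modification, 78.8% had H3K27me3 alone and 14.1% had neither, so the class of a probe also changed where no change was called. Their H3K79me2 mean was -0.10 on Day2 and 0.47 on Day7. Probes marked by H3K27me3 on Day2 and not called on Day4 also had more H3K79me2 later, at -0.05 on Day2 and 0.54 on Day7, while their H3K27me3 was still at 1.76 on Day7.

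At the set of 772 probes with an H3K27me3 fall by Day4, the means of both other modifications were higher, while 365 of the probes were called as H3K4me3 rises and H3K79me2 had no test. The H3K4me3 mean changed by 1.29 and H3K79me2 by 1.86 from Day2, on arrays that had no part in choosing the set, in line with a gain of active marks at the same probes as a hypothesis. A rise of H3 in the reference channel alone would lower every ratio at these probes, and the H3K4me3 change of 1.29 runs against that. Chance high values on the Day2 arrays would leave the Day0 mean near that of Day4, and Day0 was 1.5 higher. Whether loss of H3K27me3 and gain of the other marks happened in the same cells stays open, as does a difference in cell makeup between stages. In the wider set called without the discordant arrays the H3K4me3 change was 0.23 and 10.3% of the probes were called as H3K4me3 rises, so the strength of the relation depends on which probes are called.

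The H3K27me3 array of Day2+RA replicate 1 had 2108 probes at 2 or more that were low on Day2. On replicate 2 of that stage their median was -0.35, which argues against a change brought by retinoic acid. Their median H3K79me2 log ratio on Day2+RA was 1.29, so DNA that carries H3K79me2 in the material of that array is a candidate explanation. A full swap with the H3K79me2 array is argued against, since the array correlated better with H3K27me3 replicate 2 than with that array, by 0.44 (0.57 against 0.13). The presence of such DNA on the array was not shown, and how it would have come there stays open. The same array and the H3K4me3 array of that replicate also lacked 181 and 321 values, against 39 and 9 on the second replicates.

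The H3K27me3 array of Day3 had 1627 such probes, without the same sign. Their median H3K79me2 log ratio on Day3 was -0.0064, which argues against the explanation above for this array. The residuals of neighbouring feature numbers correlated at 0.012, below the highest of the other H3K27me3 arrays (0.080, on Day7). If numbers follow the layout, this argues against a defect over a large area of the surface. A correlation over all features could miss a small patch, and the Day7 array was not shown to be free of one. Random gain and loss of fragments cannot be told apart from a true change of the stage: of 7990 probes at 2 or more on all Day2 and Day4 arrays, 2.75% lay under 0.5 on Day3, between the bounds of 1% and 5% set in advance. The same share was 4.56% on Day2+RA replicate 1, 0.476% on Day0 replicate 1 and 0.313% on Day7. A change that is confined to Day3 was not excluded, since that stage had 1 array of H3K27me3.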
